A study of Homo sapiens with 12 samples.

How the data were processed

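Gene expression was measured on 12 arrays, each hybridized with total RNA of a culture of the human tumour line PC14 and mouse cells after 2 rounds of co-culture. The 4 groups of 3 arrays were the 4 orders of astrocytes and NIH 3T3 fibroblasts as partners. Per the labels, 500 ng of RNA was labelled with biotin as cRNA and hybridized to the Illumina Human-6 BeadChip version 2 with 48697 probes, and the gene profile was exported from BeadStudio, whose version is not given. No step is named that would remove mouse RNA before labelling.

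The authors deposited 2 tables. The first holds the deposited intensity of each probe before normalization, from 15.3 to 37817.9, with no subtraction of background and no detection p-values. The second holds values that the authors made as log2 of the same intensity, quantile normalized between arrays. The first table names probes only by their address on the array. It was joined to the second through the values: each of the 48687 probes matched 1 entry within 0.0005 after the same transformation, the next nearest entry was at least 0.0297 away, and all 12 columns matched their own sample. Probe identifiers and gene symbols came from the platform annotation, which gave 1 gene for 23675 probes, several for 35 and none for 24977, and 23639 of the symbols were found in the reference table of genes. No genome build is given, so no coordinates are reported.

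The deposited intensity was background corrected with the normexp model (offset 50), quantile normalized between the 12 arrays and put on the log2 scale. Probes with a mean at or above the median of all probes (5.94) were tested, 24344 of 48687, which covered 13020 genes; the upper quartile was 6.15. One model of 4 group means was fitted to each probe with limma 3.58.1 in R 4.3.3, with moderated variances, 8 residual degrees of freedom and no block. Differences are astrocytes minus NIH 3T3. The 7 comparisons were the second partner averaged over the first, the first partner averaged over the second, their interaction, and the simple effect of each partner at each level of the other. P-values were adjusted by Benjamini and Hochberg over the tested probes within each comparison, and an adjusted p under 0.05 was a call. For genes with several probes the one with the highest mean was used. The genes named are those called with the largest difference, 10 in each direction for the averaged comparisons and the interaction and 5 in each direction for the simple effects, without provisional symbols. BCL2L1, GSTA5 and TWIST1 were always named, and from each gene list up to 4 members with the smallest p.

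Gene lists fixed before the data were examined were tested with camera of limma at a preset correlation of 0.01, adjusted over the 31 lists within a comparison. An estimated correlation and the fry test were run beside it. The lists covered BCL2L1, GSTA5 and TWIST1, apoptosis, glutathione and NRF2, drug transporters, endothelin and gap junctions, STAT3, interferon, NF-kB, hypoxia, glycolysis, cholesterol, ATF4 and the unfolded protein response, mesenchymal and epithelial genes, TGF-beta, Notch, G1/S, G2/M, immediate early genes, MAPK feedback, heat shock, metallothioneins, antigen presentation, ribosomal proteins, mitochondrial respiration, lung lineage, and markers of astrocytes, fibroblasts, microglia, and oligodendrocytes with neurons. After the data were seen 3 lists were added: the melanocyte lineage, fatty acid synthesis and histones, adjusted over these 3 within a comparison. Principal components, correlations of differences across probes and overlaps of called probes were computed from the same fit, and figures and summaries used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

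Before the data were examined these alternatives were chosen: the values normalized by the authors, median scaling, no background correction (floor 32), an offset of 16, no filter, a filter at the upper quartile, the replicate number as a block, trended and robust variances, array weights, a minimum of 2-fold, fits of only the groups compared, and leaving out each array in turn. After the medians of the arrays had been seen, a fit with the brightness set as a block, fits within the brighter and within the dimmer set, and cyclic loess normalization were added. Random assignments of the 12 arrays to the groups (100, seed 1) and the 10 splits of each 6 arrays were fitted as well. For the interaction, residuals of the model without it were permuted 100 times over the 12 arrays, and 100 times within the brightness sets with the block, a test added after the data had been seen.

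The fit was tested on simulated data in which 100 probes per size were moved among 24344. At a log2 difference of 1 it recovered 99% for the second partner, 98% for the first partner and 93% for the interaction, and 96% to 99% for the simple effects; at 0.5 it recovered 94%, 90% and 47%, and 80% to 83%. Of the calls 3.2% to 9% were false. A list of 15 probes moved by 0.3 was called and none of 30 lists left unmoved was. The simulated noise was independent between probes and held no brightness sets, and the lists were random probes. These shares therefore need not hold for the real arrays and lists, whose values are correlated. No sample was left out, and no test for outlying arrays was made within groups of 3.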

Results

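A human cell line, which the labels call PC14 and describe as lung cancer, was grown together with mouse cells in 2 successive rounds of co-culture. The mouse partner of each round was either astrocytes, the support cells of the brain that surround neurons and blood vessels, or NIH 3T3, an established mouse fibroblast line. Total RNA of the co-cultured cells was hybridized to human expression arrays, and the labels name no step that separated human from mouse RNA. The 12 arrays formed 4 groups of 3, named here by the order of the partners: AA (astrocytes, then astrocytes), TA (NIH 3T3, then astrocytes), AT (astrocytes, then NIH 3T3) and TT (NIH 3T3, then NIH 3T3). A digit after the letters gives the array, as in AA1. The labels do not say whether the 3 arrays of a group came from separate cultures, so the p-values measure only the spread between these arrays, and the number of arrays limits the precision of every value.

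The mean probe signal was 159.5, 154.2 and 87.8 on AA1, AA2 and AA3, and 156.1, 100.9 and 98 on TA1, TA2 and TA3. It was 182.3, 179.8 and 118.7 on AT1, AT2 and AT3, and 222.2, 139.1 and 146.8 on TT1, TT2 and TT3. By median signal the arrays parted into a brighter set of 6 (AA1, AA2, TA1, AT1, AT2 and TT1, medians of 43.5 to 45.5) and a dimmer set of 6 (AA3, TA2, TA3, AT3, TT2 and TT3, medians of 35.1 to 37.3). Each set held 3 arrays of each second partner, while the first partner was astrocytes on 4 arrays of the brighter set and 2 of the dimmer set. TA and TT thus held 1 array each in the brighter set, as AA and AT did in the dimmer set, and fits within a set took a lone array to vary like the other groups. Within both sets the mean signal was lower with astrocytes as the second partner. It was 156.6 against 194.8 in the brighter set and 95.5 against 134.8 in the dimmer set. After normalization the first principal component held 55.3% of the variance and ordered the groups. Mean scores were -21 ± 3.1 (SD, n = 3) for AA, -14.6 ± 4 for TA, 6.1 ± 1.8 for AT and 29.5 ± 6 for TT.

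**Figure D1:**
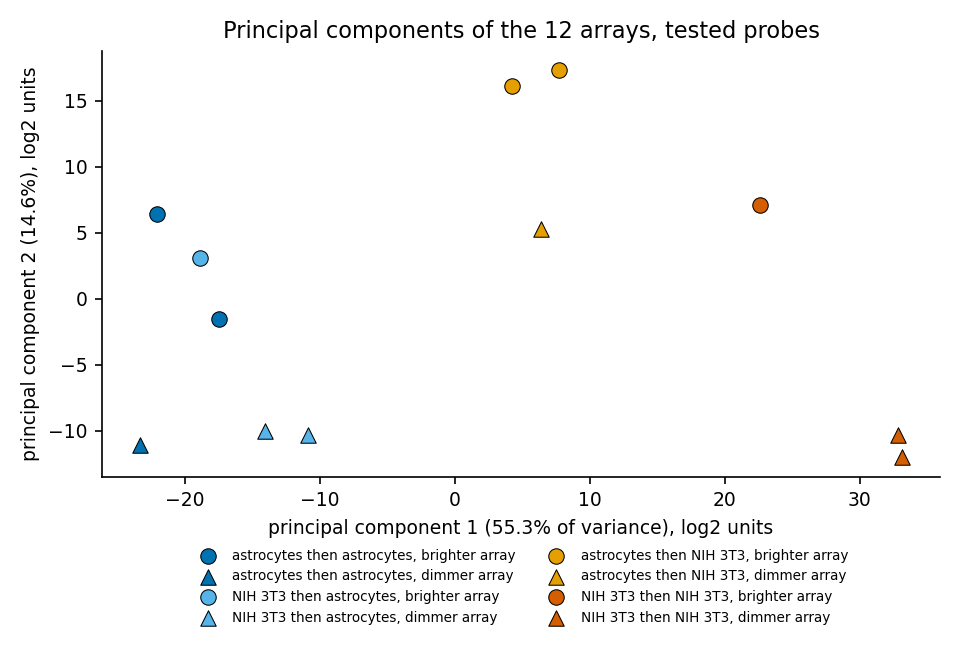
Scores of the 12 arrays on the first and second principal components of the normalized log2 signal (55.3% and 14.6% of the variance), coloured by group, with the marker shape giving the brightness set. The 6 arrays with astrocytes second lie on one side of the first component and the TT arrays lie farthest on the other, at a mean score of 29.5.

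The first comparison asked how expression depended on the partner present in the second round, averaged over the first partner. EFNB2, which encodes the Eph receptor ligand ephrin-B2, was higher with astrocytes second by 4.04 ± 0.11 on the log2 scale (SE, n = 6 per arm), and GPM6B, a proteolipid-family membrane glycoprotein abundant in neural cells, by 3.50 ± 0.05. DLK1, a membrane protein related to Notch ligands and known from fat cell precursors, fell by 4.12 ± 0.08. DCN, which encodes the matrix proteoglycan decorin, fell by 2.23 ± 0.09. The lists of immediate early genes, NF-kB targets and TGF-beta targets were called higher with astrocytes second, with 11 of 14, 7 of 12 (2 fell) and 7 of 13 (1 fell) tested members passing upward. The lists of cholesterol synthesis, mitosis and mitochondrial respiration were called lower, with 6 of 11, 12 of 20 (1 rose) and 11 of 16 passing downward, and the mitosis call ended with an estimated correlation (adjusted p = 0.0976).

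EFNB2 averaged 11.58 ± 0.39 (SD, n = 3) in AA and 11.24 ± 0.05 in TA, against 7.79 ± 0.19 in AT and 6.95 ± 0.08 in TT. GPM6B stood at 11.90 ± 0.02 and 11.88 ± 0.06 in AA and TA and at 8.11 ± 0.16 and 8.67 ± 0.09 in AT and TT. The other genes with the largest rises were PDLIM7, an actin-binding adaptor (3.70 ± 0.07), FBLN1, which encodes the matrix protein fibulin 1 (3.17 ± 0.06), and APOE, the lipid carrier that astrocytes secrete (2.76 ± 0.04). RENBP (2.74 ± 0.14), NREP (2.67 ± 0.06), the transcription factor TCF4 (2.50 ± 0.08), the double-stranded RNA sensor IFIH1 (2.48 ± 0.06) and NFKBIA, the inhibitor of NF-kB (2.47 ± 0.08), followed. Those with the largest falls after DLK1 and DCN were RAB42 (-1.66 ± 0.10), ZFHX4 (-1.53 ± 0.06), GLT8D2 (-1.39 ± 0.06), and the homeobox gene MEIS1 (-1.14 ± 0.07). They were followed by STEAP1 (-1.05 ± 0.08), SLC18B1 (-0.94 ± 0.07), EFEMP1 (-0.89 ± 0.16) and the actin gene ACTG1 (-0.88 ± 0.20). The fold changes of these 20 genes were 1.84 to 17.38. For EFEMP1 and ACTG1 the arrays of the arms overlapped. The other tested probe of FBLN1 was not called, here or in the comparison at either first partner. Of the 2 other tested probes of GPM6B and of STEAP1, 1 each was called in the same direction. With astrocytes second, DLK1, DCN, RAB42, ZFHX4 and GLT8D2 lay near the median probe of 5.94, as APOE and FBLN1 did with NIH 3T3 second, so background hides part of their differences. Each of these genes was thus seen with only one of the partners second. Mouse RNA of that partner binding to the probes could also give such a signal. This was not tested, so the differences cannot be assigned to the tumour cells.

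BCL2L1, the gene of the anti-apoptotic protein BCL-XL, the glutathione S-transferase gene GSTA5 and TWIST1, a transcription factor of mesenchymal cells, were examined in every comparison. These 3 genes came from knowledge of published work on tumour cells and astrocytes that may include these arrays, so their direction is not independent evidence. BCL2L1 was higher with astrocytes second by 1.56 ± 0.10 (SE, n = 6 per arm, adjusted p = 4.36e-07), GSTA5 by 1.08 ± 0.07 (adjusted p = 3.65e-07) and TWIST1 by 0.59 ± 0.13 (adjusted p = 0.00615). In each gene the 6 arrays of one arm lay above the 6 of the other. Group means of BCL2L1 were 10.14 ± 0.22 (SD, n = 3) in AA, 9.66 ± 0.20 in TA, 8.84 ± 0.07 in AT and 7.85 ± 0.25 in TT. GSTA5 averaged 7.98 ± 0.14, 7.55 ± 0.19, 7.04 ± 0.08 and 6.34 ± 0.04 in the same order, and TWIST1 averaged 6.58 ± 0.48, 6.34 ± 0.14, 5.87 ± 0.17 and 5.87 ± 0.04. In AT and TT TWIST1 thus lay below the median probe of 5.94, so background can hide part of its differences in every comparison that uses these groups.

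**Figure D2:**
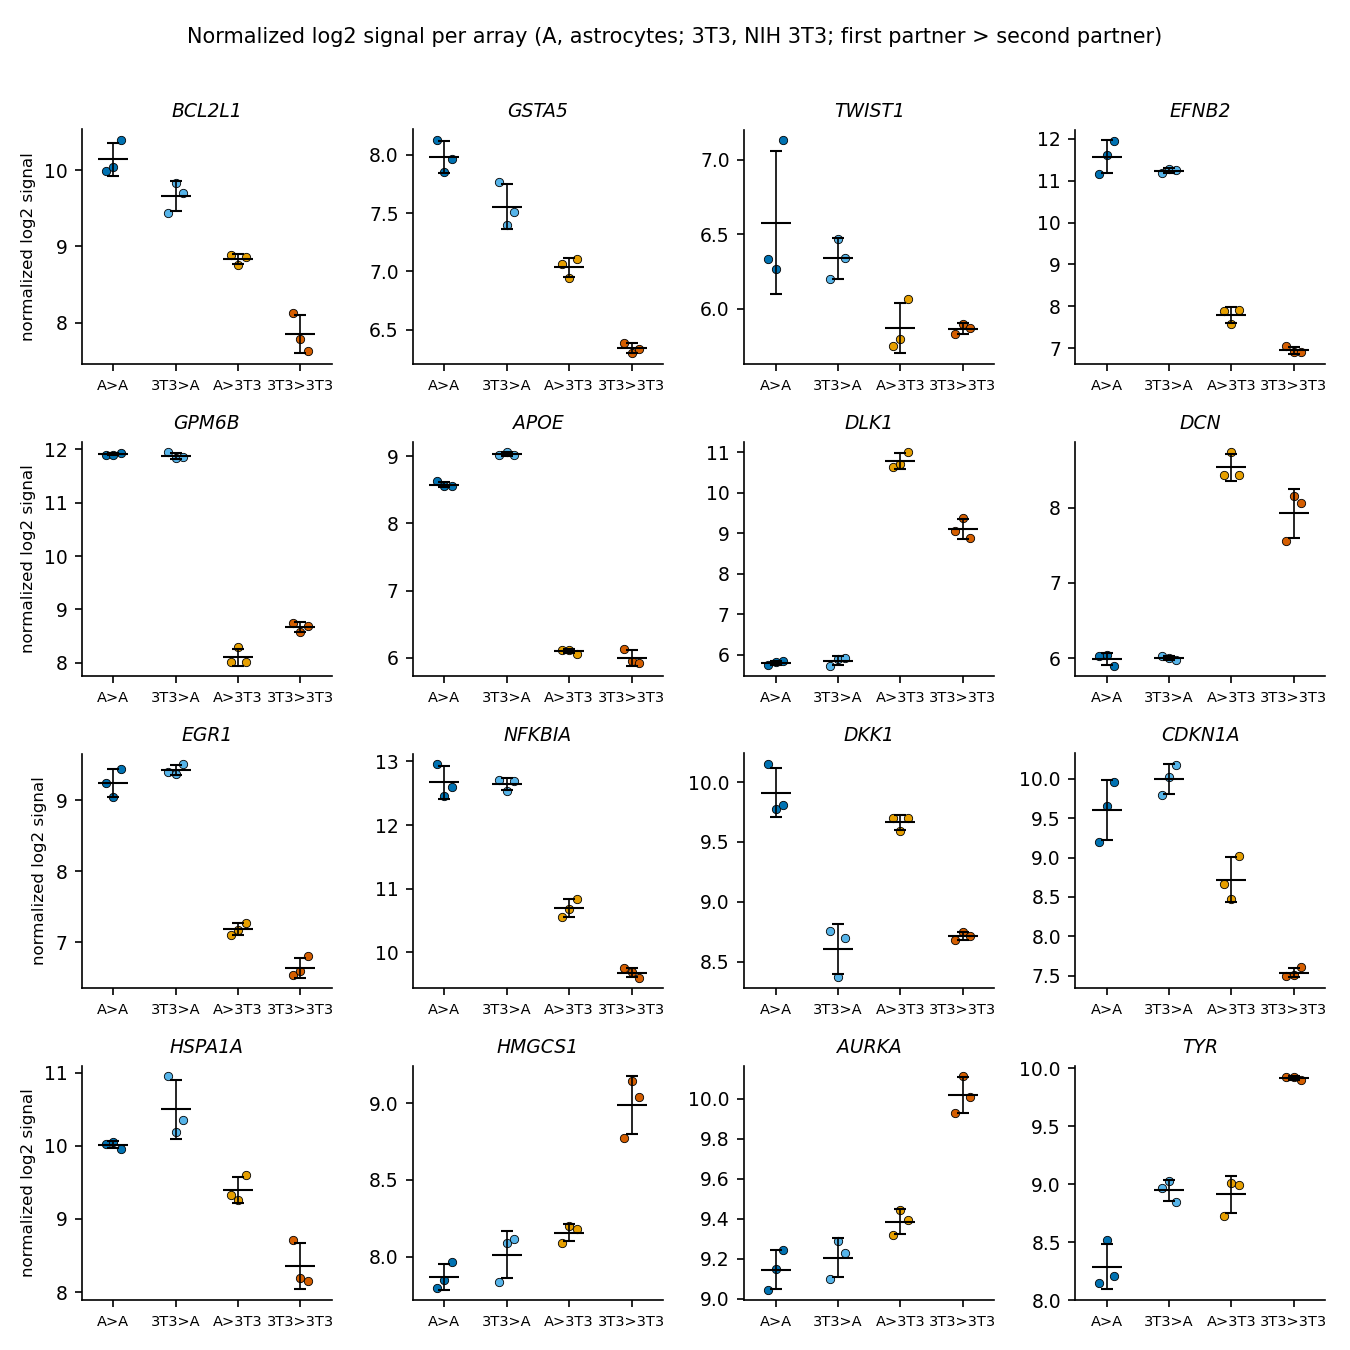
Normalized log2 signal of 16 genes on each of the 12 arrays (points), with the mean and SD of each group of 3 arrays (bars). BCL2L1 falls from a mean of 10.14 in AA to 7.85 in TT, while DLK1 lies near the median probe in AA and TA and at 10.79 and 9.11 in AT and TT.

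Among 31 gene lists, 13 differed from the other genes by the camera test. The immediate early genes, which respond first to growth signals, had 11 of 14 tested members higher with astrocytes second and 3 not passing (adjusted p = 2.61e-09). Among them were EGR1 (2.42 ± 0.07), FOS (0.97 ± 0.05) and FOSB (0.48 ± 0.05). Of the NF-kB targets 7 of 12 rose and 2 fell (adjusted p = 0.00078). NFKBIA rose as given, the cytokine gene CXCL8 rose by 0.65 ± 0.07, and the chemokine gene CCL2 fell by 0.72 ± 0.08. Of the TGF-beta and BMP targets 7 of 13 rose and 1 fell (adjusted p = 0.000629), including PMEPA1 (1.06 ± 0.11), TGFB2 (1.05 ± 0.08) and CCN2 (0.75 ± 0.04). The list of BCL2L1, GSTA5 and TWIST1 had 3 of 3 members higher (adjusted p = 0.000337). For these 4 lists the counts adjusted over the list alone were the same.

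A further 6 lists were called higher, and with median scaling between arrays their calls ended and their means turned below 0. That scaling lowered the mean of every one of the 31 lists, by 0.12 to 0.51, so the change of sign is not particular to these 6. The hypoxia genes had 6 of 17 members up and 1 down with a mean of 0.17, which was -0.19 with median scaling (adjusted p = 0.00323). In it ADM, the vasodilator adrenomedullin, was higher by 1.17 ± 0.06. The MAPK feedback genes had 7 of 13 up and 3 down (8 and 3 adjusted over the list alone) with a mean of 0.25, or -0.18 with median scaling (adjusted p = 0.00323, and 0.0684 with an estimated correlation). The phosphatase gene DUSP5 was higher by 1.16 ± 0.07. The genes of ATF4 and the unfolded protein response had 7 of 17 up and 2 down with a mean of 0.2, or -0.28 with median scaling (adjusted p = 0.0066, and 0.176 with an estimated correlation). PPP1R15A led them at 1.03 ± 0.05. The interferon-stimulated genes had 4 of 20 up and 1 down (5 and 1 adjusted over the list alone) with a mean of 0.25, or -0.09 with median scaling (adjusted p = 0.00961, and 0.0976 with an estimated correlation). IFIH1 and IFIT2 (0.94 ± 0.05) led them. The IL6 and STAT3 targets had 4 of 16 up (5 up and 1 down adjusted over the list alone) with a mean of 0.17, or -0.05 with median scaling (adjusted p = 0.0107, and 0.0684 with an estimated correlation). The kinase gene PIM1 led them at 1.10 ± 0.09. The heat shock genes had 4 of 12 up and 1 down with a mean of 0.33, or -0.17 with median scaling (adjusted p = 0.0195, and 0.134 with an estimated correlation). Here HSPA1B led at 1.53 ± 0.10. With median scaling the calls of ADM (0.59), PPP1R15A (0.47) and PIM1 (0.51) ended as well.

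The means of the 3 lists called lower were -0.28, -0.24 and -0.27, and -0.23, -0.19 and -0.19 with cyclic loess. Of the genes of cholesterol synthesis and uptake 6 of 11 fell (8 adjusted over the list alone, adjusted p = 0.00233), including HMGCS1 (-0.63 ± 0.07), IDI1 (-0.54 ± 0.08) and SQLE (-0.27 ± 0.04). Of the genes of G2/M and mitosis 12 of 20 fell and 1 rose (14 and 1 adjusted over the list alone, adjusted p = 0.00114, and 0.0976 with an estimated correlation). The mitotic kinase genes CDK1 (-0.59 ± 0.09) and AURKA (-0.53 ± 0.05) fell. Of the genes of mitochondrial respiration 11 of 16 fell (14 adjusted over the list alone, adjusted p = 0.000337), including COX4I1 at -0.35 ± 0.04. The calls that held with an estimated correlation were those of BCL2L1, GSTA5 and TWIST1, NF-kB, hypoxia, TGF-beta, immediate early genes, cholesterol and mitochondrial respiration, 7 of 13. No called list had a median, mean and test of different sign.

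The remaining 18 lists were not called by camera for the second partner, and no direction is given for them here. The fry test, run beside camera, called 10 of them. In the apoptosis lists 2 anti-apoptotic genes rose and 3 fell of 8 (adjusted p = 0.817), and 4 pro-apoptotic genes rose and 3 fell of 11 (4 and 4 adjusted over the list alone, 0.744). Members rose and fell in numbers of 1 and 2 of 14 among glutathione and NRF2 targets (0.817) and 3 and 1 of 14 among glycolysis genes (0.0967). They did so in 4 and 2 of 9 among mesenchymal genes (4 and 3 adjusted over the list alone, 0.317), 1 and 2 of 6 among epithelial genes (0.817), 1 and 1 of 3 in the endothelin and gap junction list (0.475) and 2 and 1 of 10 among antigen presentation genes (3 and 1 adjusted over the list alone, 0.277). Of the G1/S genes 4 of 17 fell (5 adjusted over the list alone, 0.0967), of the drug transporters 2 of 4 fell (0.275). Of the ribosomal protein genes 2 of 16 fell, neither of which passed over the list alone (0.701). Of the Notch genes 2 of 8 rose (0.417), of the metallothionein list 2 of 7 (2 up and 2 down adjusted over the list alone, 0.28), and of the lung lineage genes 1 of 3 (0.485).

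Markers of the cells in the partner cultures moved both ways. Of the astrocyte markers 2 rose and 2 fell of 14 (camera adjusted p = 0.483), APOE by the value above while FABP7, a fatty acid binding protein of radial glia, fell by 0.86 ± 0.07. FABP7 had its highest mean, 10.09, in TT, where no partner was astrocytes. Its signal there thus came from other cells, and its fall is no measure of astrocyte RNA. Of the fibroblast markers 4 rose and 5 fell of 14 (4 and 6 adjusted over the list alone, 0.659), with DCN the largest. Of the microglia and macrophage markers 1 rose and 2 fell of 6 (0.817), and of the oligodendrocyte and neuron markers 2 rose and 1 fell of 10 (0.694). Other lists not followed by a count over the list alone had the same count there. In signal, 7 of 18 astrocyte markers and 11 of 22 fibroblast markers on the array lay above the upper quartile of all probes. The fry test called the astrocyte markers higher with astrocytes second (mean of 0.15, adjusted p = 1.97e-06). It called the fibroblast markers lower (mean of -0.18, adjusted p = 0.00107). With median scaling these means were -0.02 and -0.47. Whether RNA of the partner cells gave these differences was not tested.

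Over all probes, limma called 2022 higher and 3074 lower with astrocytes second among 24344 tested, 194 and 8 of them by at least 2-fold. With the brightness set as a block 6025 probes were called, within the brighter set 1668 and within the dimmer set 5694. Across probes the differences of the 2 sets correlated with r = 0.87. With median scaling, which keeps the lower signal of the arrays with astrocytes second, 6069 of 6385 second partner calls were lower, so the balance of rises and falls is relative to equal total signal. Within the brighter set the call of EFEMP1 ended (-0.65, adjusted p = 0.0515). Within the dimmer set those of the interferon list (mean of 0.23, 0.0533) and the unfolded protein response list (0.16, 0.0606) ended.

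The comparison was also made at each first partner, on separate arrays. After astrocytes, AA against AT, GPM6B was higher by 3.80 ± 0.07 (SE, n = 3 per arm), EFNB2 by 3.79 ± 0.15, PDLIM7 by 3.32 ± 0.09, FBLN1 by 3.09 ± 0.09 and RENBP by 2.77 ± 0.20. There were falls in DLK1 (-4.98 ± 0.12), DCN (-2.54 ± 0.13), RAB42 (-2.28 ± 0.14), ZFHX4 (-1.91 ± 0.08) and GLT8D2 (-1.80 ± 0.09). After NIH 3T3, TA against TT, EFNB2 was higher by 4.29 ± 0.15, PDLIM7 by 4.09 ± 0.09, FBLN1 by 3.25 ± 0.09, GPM6B by 3.21 ± 0.07 and NREP by 3.09 ± 0.09. Falls followed in DLK1 (-3.26 ± 0.12), DCN (-1.92 ± 0.13), ACTG1 (-1.34 ± 0.28), TUBA1A (-1.34 ± 0.19) and ARHGEF3 (-1.24 ± 0.11). BCL2L1 was higher by 1.31 ± 0.14 after astrocytes (adjusted p = 0.00011) and by 1.81 ± 0.14 after NIH 3T3 (4.18e-06), and GSTA5 by 0.94 ± 0.09 (7.08e-05) and 1.22 ± 0.09 (4.56e-06). TWIST1 was higher by 0.71 ± 0.18 (0.0411) after astrocytes, while after NIH 3T3 its difference was 0.47 ± 0.18 (0.102). The latter passed within the dimmer set (0.000559), with the brightness block (0.0167) and with median scaling (0.0346), though not within the brighter set, where each arm was 1 array (0.133). It also passed with the authors' values, no background correction, the offset of 16, the stricter filter, the replicate block, array weights and cyclic loess, and without AA3.

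After astrocytes 792 probes were higher and 675 lower, and after NIH 3T3 1920 were higher and 2563 lower. Of these, 682 were higher in both, against 62.5 for independent lists, 409 were lower in both, against 71.1, and 17 were called in opposite directions. Across the 24344 probes, which are not independent replicates, the differences of these separate arrays correlated with r = 0.73 and rho = 0.52. With median scaling 68 probes were called after astrocytes and the calls of BCL2L1 (0.85), GSTA5 (0.56) and TWIST1 (0.55) there ended, and within the brighter set 509 and 803 probes were called. The count after astrocytes was 941 without AA3 and 910 without AT2, and that after NIH 3T3 was 2970 without TT3. TWIST1 after astrocytes lost its call without TA2 (0.0557), TA3 (0.0626), AT1 (0.133), AT2 (0.132), TT2 (0.0554) or TT3 (0.0588).

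The second comparison asked what remained of the first partner after the second round, averaged over the second partner. DKK1, which encodes a secreted inhibitor of Wnt signalling, was higher on the arrays with astrocytes first by 1.13 ± 0.08 (SE, n = 6 per arm, adjusted p = 7.09e-05), and the keratin gene KRT80 by 0.83 ± 0.09. TYR, the gene of the pigment enzyme tyrosinase, fell by 0.83 ± 0.07 (adjusted p = 0.000146). BHLHE40, a transcription factor of the stress and clock response, fell by 0.62 ± 0.06. The list of ATF4 and the unfolded protein response was called higher with astrocytes first (6 of 17 rose and 1 fell), as was that of immediate early genes (4 of 14 rose), and that of mitochondrial respiration was called lower (5 of 16 fell). The calls of the first 2 ended with an estimated correlation (adjusted p = 0.186 and 0.207) and that of the third with median scaling (0.0684). The largest differences were smaller than those of the second partner, with 6 probes higher by at least 2-fold against 194 there. Among called probes the median absolute log2 difference was similar, 0.31 against 0.3 for the second partner.

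DKK1 averaged 9.91 ± 0.21 (SD, n = 3) in AA and 9.66 ± 0.06 in AT, against 8.61 ± 0.21 in TA and 8.71 ± 0.03 in TT. Other genes with the largest rises were SIGLEC12 (1.02 ± 0.17), TSHZ1 (0.90 ± 0.11), the interferon-induced IFITM1 (0.87 ± 0.16), the transcription factor NFIX (0.86 ± 0.15), CITED2 (0.85 ± 0.17), the cytoskeletal regulator DPYSL3 (0.84 ± 0.12) and DLK1 (0.81 ± 0.08). Those with the largest falls were SPATS1 (-0.78 ± 0.08), FABP7 (-0.69 ± 0.07), RTKN (-0.60 ± 0.10), the TGF-beta co-receptor TGFBR3 (-0.58 ± 0.09), MSRB2 (-0.57 ± 0.05) and TBC1D16 (-0.56 ± 0.05). UBE2NL (0.91 ± 0.22), ATP5MC1 (-0.62 ± 0.13) and CHCHD10 (-0.56 ± 0.12) complete the 20 genes. They lost their calls without 8, 3 and 2 of the arrays, with adjusted p of 0.0933, 0.0589 and 0.0579 without TA2 in each case. Among the 20, the arrays of the arms overlapped for all except DKK1, KRT80, SPATS1, TGFBR3 and MSRB2, and they did so for BCL2L1 and GSTA5. These arms pool both second partners, so a second partner difference can make them overlap. At each second partner taken alone, the arms of BCL2L1 and of GSTA5 were apart, while those of TWIST1 overlapped. With 3 arrays per arm, chance parts the arms of a gene in 10% of cases. BCL2L1 was higher by 0.74 ± 0.10 (adjusted p = 0.00169) and GSTA5 by 0.56 ± 0.07 (0.000882), while TWIST1 differed by 0.12 ± 0.13 (0.7). Within the dimmer set, which holds 1 array each of AA and AT, the TWIST1 difference was 0.45. The other tested probes of BCL2L1, SIGLEC12 and RTKN were not called here. For the second partner, the other probe of BCL2L1 was called in the same direction.

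Of the 31 lists 7 were called for the first partner, with no mean changing sign under median scaling or cyclic loess. Of the genes of ATF4 and the unfolded protein response 6 of 17 rose and 1 fell (8 and 1 adjusted over the list alone, camera adjusted p = 0.000495, and 0.186 with an estimated correlation). The asparagine synthetase gene ASNS rose by 0.65 ± 0.06 and CTH by 0.52 ± 0.05, while the chaperone gene HSPA5 fell by 0.36 ± 0.06. Of the immediate early genes 4 of 14 rose (6 up and 1 down adjusted over the list alone, adjusted p = 0.00335, and 0.207 with an estimated correlation). CCN1 (0.60 ± 0.07) and FOSL1 (0.32 ± 0.05) were among them. Of the genes of mitochondrial respiration 5 of 16 fell (10 adjusted over the list alone, adjusted p = 2.18e-05, and 0.0396 with an estimated correlation), including COX4I1 (-0.19 ± 0.04). With median scaling this call ended (0.0684), while the mean of the list was -0.23 before and -0.24 with it. BCL2L1 and GSTA5 gave their list of 3 its call (2 of 3 up, adjusted p = 0.00241, and 0.114 with an estimated correlation). The remaining 24 lists were not called by camera. Among them 2 of 14 astrocyte markers fell (0.185) and 3 of 14 fibroblast markers rose and 1 fell (5 and 1 adjusted over the list alone, 0.0823). The fry test called 7 of the 24. Among these were the astrocyte markers, lower with astrocytes first (mean of -0.08, adjusted p = 0.00407), and the fibroblast markers, higher (0.11, 0.0084).

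The calls of 3 further lists depended on single arrays and ended with the stricter filter (adjusted p = 0.0821 for each). Of the NF-kB targets 4 of 12 rose (adjusted p = 0.0289, and 0.207 with an estimated correlation), with NFKBIA at 0.52 ± 0.08 and CCL2 at 0.40 ± 0.08. This call ended without AT3 (0.0798) or TT1 (0.0812) and with no filter (0.0858). Of the cholesterol genes 1 of 11 fell, HMGCS1 at -0.49 ± 0.07 (adjusted p = 0.0419, and 0.186 with an estimated correlation), a call that ended without AA2 (0.0524), AA3 (0.0828), TA1 (0.0919), AT3 (0.0798) or TT1 (0.11). Of the genes of G2/M and mitosis 3 of 20 fell (5 adjusted over the list alone, adjusted p = 0.0476, and 0.28 with an estimated correlation), including AURKA (-0.35 ± 0.05) and CENPE (-0.32 ± 0.07). The call of this list ended without AA3 (0.0828), TA2 (0.0527), TA3 (0.0724), AT1 (0.083), AT3 (0.0702) or TT1 (0.11), and with an offset of 16 (0.0531). The counts of the first 2 of these lists did not change when adjusted over the list alone.

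**Figure D3:**
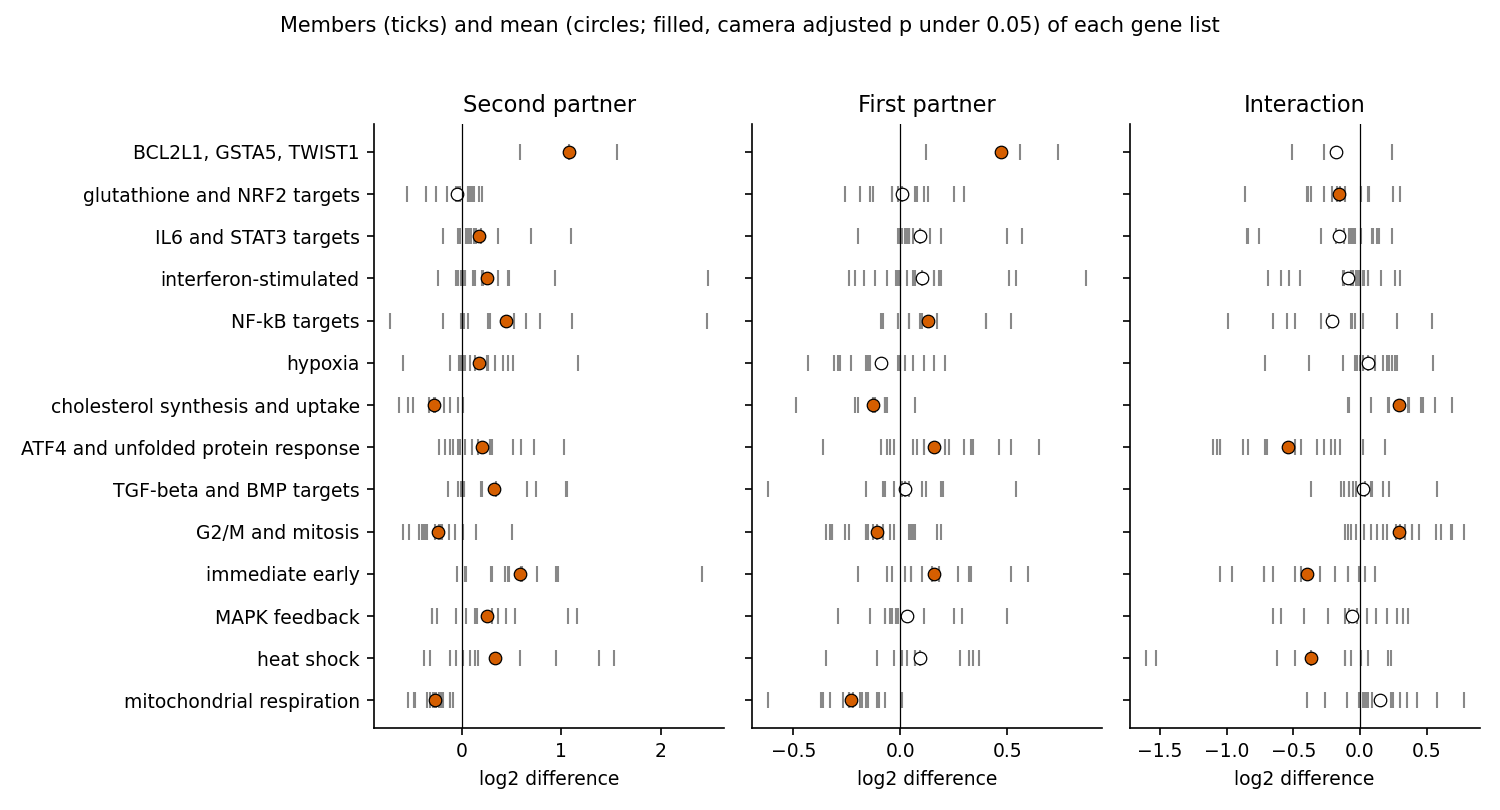
Log2 difference of the tested members (ticks) and their mean (circles, filled where the camera adjusted p was under 0.05) of 14 gene lists in the second partner, first partner and interaction comparisons, positive values meaning higher with astrocytes. For the second partner the immediate early genes have a mean of 0.59 and mitochondrial respiration genes one of -0.27, while with median scaling, which lowers every list there, the means of the STAT3, interferon, hypoxia, unfolded protein response, MAPK and heat shock lists turn below 0, as that of the glutathione list in the interaction turns above 0.

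Over all probes 792 were higher and 638 lower with astrocytes first, and 1449 were called with the brightness set as a block. Within the brighter set limma called 0 probes (2151 at unadjusted p under 0.05), within the dimmer set 3082, and with median scaling 4 (2380 at unadjusted p under 0.05). The calls of all 20 named genes and of BCL2L1 and GSTA5 ended in the brighter set and with median scaling. The differences of DKK1 there were 1.09 and 1.05, those of TYR -0.85 and -0.89, those of BCL2L1 0.64 and 0.69, and those of GSTA5 0.42 and 0.52. Across probes r between the differences of the 2 sets was 0.46. The count was 758 without TA2, 891 without TA3, 903 without AT1, 2586 without TT1, 934 without TT2 and 776 without TT3. Within the brighter set the calls of the NF-kB (mean of 0.12, adjusted p = 0.0535), immediate early (0.1, 0.109) and mitosis (-0.08, 0.143) lists ended.

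With astrocytes second, AA against TA, limma called 24 probes higher and 19 lower. DKK1 was higher by 1.30 ± 0.11 (SE, n = 3 per arm, adjusted p = 0.000664), DACT1, an intracellular regulator of Wnt signalling, by 0.78 ± 0.09 and the chondroitin synthase gene CHSY3 by 0.67 ± 0.05. CNOT3 (0.72 ± 0.11), IFIH1 (0.69 ± 0.09), TYR (-0.66 ± 0.10), BHLHE40 (-0.66 ± 0.08), FOS (-0.56 ± 0.08), the glucose transporter gene SLC2A3 (-0.54 ± 0.09) and COL9A1 (-0.50 ± 0.07) also passed, but lost their calls without 1 to 8 of the arrays. Adjusted p was 0.0619 for IFIH1 without TA3. Without TA2 it was 0.156 for CNOT3, 0.145 for TYR, 0.0695 for BHLHE40, 0.0742 for FOS, 0.175 for SLC2A3 and 0.0742 for COL9A1. With cyclic loess the calls of CNOT3 (0.65, adjusted p = 0.115), CHSY3 (0.59, 0.0827), TYR (-0.63, 0.0703), FOS (-0.47, 0.238), SLC2A3 (-0.50, 0.14) and COL9A1 (-0.43, 0.0703) ended, 6 of these 10 genes. BCL2L1 differed by 0.48 ± 0.14 (0.257), GSTA5 by 0.42 ± 0.09 (0.13) and TWIST1 by 0.24 ± 0.18 (0.795). Within the dimmer set, where AA was the single array AA3, all 3 were called, at 0.63 (0.0257), 0.51 (0.0287) and 0.73 (0.012). TWIST1 stood at 7.133 on AA3 and at 6.335 and 6.265 on AA1 and AA2. GSTA5 was also called with the replicate block and without TA1 (0.53). The count was 26 without AA1, 15 without AA3, 12 without TA2, 14 without TA3 and 68 without TT1. With the brightness block it was 82 and within the dimmer set 291. Within the brighter set limma called 0 (1104 at unadjusted p under 0.05) and with median scaling 0 (429 at unadjusted p under 0.05).

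With NIH 3T3 second, AT against TT, 1064 probes were higher and 998 lower with astrocytes first. DLK1, whose signal was near the median probe without NIH 3T3 second, was higher by 1.67 ± 0.12 (adjusted p = 7.93e-05), SIGLEC12 by 1.60 ± 0.24, and NFIX by 1.49 ± 0.21. The complement inhibitor gene CD55 was higher by 1.45 ± 0.10 (7.73e-05) and FXYD5 by 1.36 ± 0.22. Falls were seen in the RING finger gene RNF150 (-1.11 ± 0.17), ARHGEF3 (-1.09 ± 0.11) and the kinase gene ABL1 (-1.06 ± 0.20). PHRF1 (-1.20 ± 0.28) and DHX9 (-1.06 ± 0.26) lost their calls without 4 and 5 of the arrays, with adjusted p of 0.104 and 0.103 without TT3. BCL2L1 was higher by 0.99 ± 0.14 (0.00139) and GSTA5 by 0.70 ± 0.09 (0.00111), while TWIST1 differed by 0.00 ± 0.18 (0.994). TWIST1 lay at 5.87 in both AT and TT, below the median probe of 5.94, so background could hide a difference there. The other tested probes of BCL2L1, SIGLEC12, ABL1 and DHX9 were not called.

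The count with NIH 3T3 second was 1105 without AT1, 1307 without AT2, 3256 without TT1, 1043 without TT2 and 918 without TT3. With the brightness block it was 2374 and within the dimmer set 3354, while it was 1 within the brighter set, where TT was the single array TT1 (DLK1 kept its call there). With median scaling it was 164, which ended the calls of SIGLEC12 (1.37 with it), NFIX (1.28), CD55 (1.25), FXYD5 (1.13), ARHGEF3 (-1.29), DHX9 (-1.23), BCL2L1 (0.79) and GSTA5 (0.66). Between the comparisons with astrocytes and with NIH 3T3 second, 15 probes were higher in both, against 1 for independent lists, 9 were lower in both, against 0.8, and 2 were opposite. Across probes the 2 sets of differences correlated with r = 0.33 and rho = 0.24, and within the brighter set with r = 0.08. The second and first partner differences, which share all 12 arrays, correlated with r = 0.56 and rho = 0.49, for which no value under no change was computed. In both, 538 probes were higher, against 65.8 for independent lists, and 426 lower, against 80.6, and 66 were opposite.

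**Figure D4:**
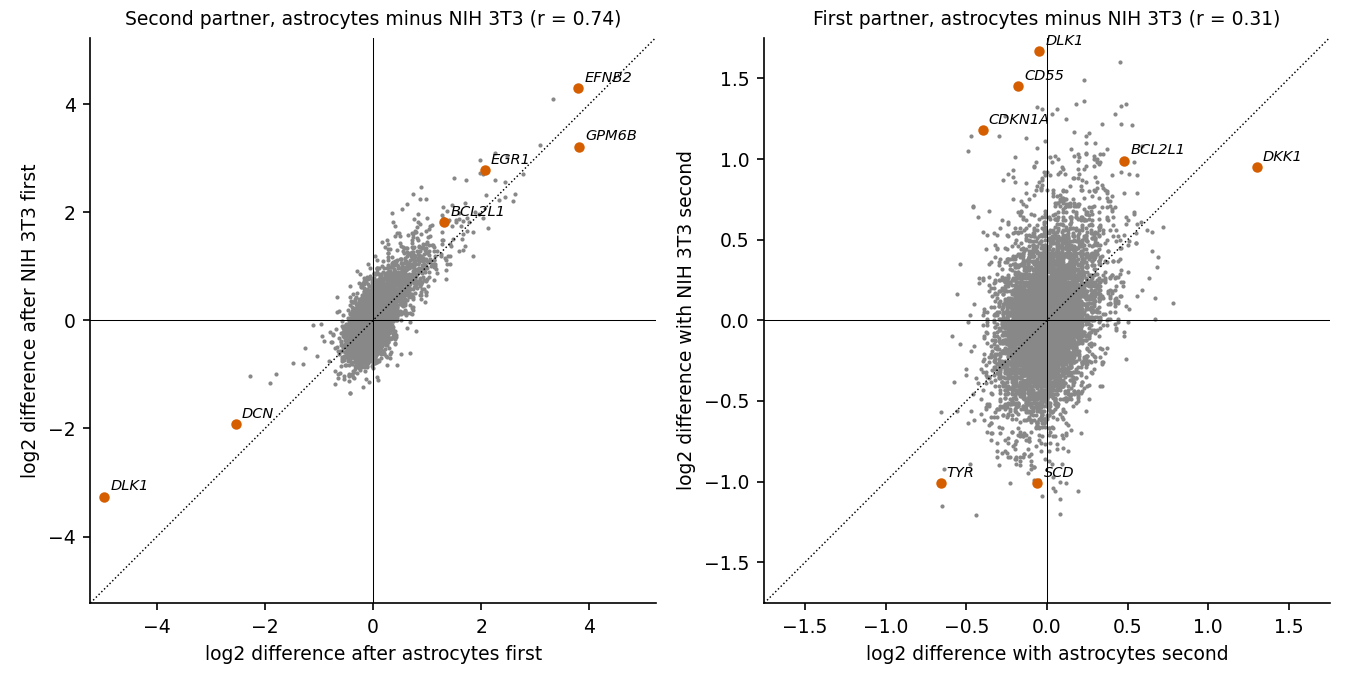
Log2 differences of 13020 genes (points), the second partner difference after NIH 3T3 against that after astrocytes (r = 0.74) and the first partner difference under NIH 3T3 against that under astrocytes (r = 0.31), positive values meaning higher with astrocytes. EFNB2 and GPM6B lie high and DLK1 low on both axes for the second partner, while for the first partner CD55 departs from 0 on the NIH 3T3 axis and DKK1 lies above 0 on both.

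The third comparison, the interaction, asked whether the second partner difference depended on the first partner. It was the signed second partner difference, astrocytes minus NIH 3T3, after astrocytes minus that after NIH 3T3. CD55 had an interaction of -1.63 ± 0.13 (SE, n = 3 per group, adjusted p = 0.000989), with group means of 9.64 ± 0.19 (SD) in AA, 9.82 ± 0.14 in TA, 9.29 ± 0.08 in AT and 7.84 ± 0.09 in TT. The cell cycle inhibitor gene CDKN1A, at -1.58 ± 0.25 (0.0157), the stress cytokine gene GDF15, at -1.53 ± 0.21 (0.00866), and the heat shock gene HSPA1B, at -1.61 ± 0.19 (0.0044), had the same shape, with the lowest mean in TT. SCD, the desaturase of fatty acid synthesis, had the opposite sign at 0.95 ± 0.14 (0.0125) and its highest mean, 9.63 ± 0.05, in TT.

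In the list of ATF4 and the unfolded protein response 8 of 17 genes had a negative interaction (12 adjusted over the list alone, camera adjusted p = 1.92e-13, and 0.0248 with an estimated correlation). They included TRIB3 (-1.10 ± 0.16), DDIT3, the pro-apoptotic factor CHOP (-1.07 ± 0.10), and PPP1R15A (-1.05 ± 0.10). Of the immediate early genes 5 of 14 did (6 adjusted over the list alone, adjusted p = 1.61e-06, and 0.0759 with an estimated correlation), such as IER3 (-0.96 ± 0.14) and FOS (-0.72 ± 0.11). Of the heat shock genes 3 of 12 did (4 adjusted over the list alone, adjusted p = 0.0102, and 0.163 with an estimated correlation). With median scaling the heat shock call ended (mean of -0.37 before and -0.1 with it, 0.202), as it did with cyclic loess (-0.32, 0.0668). The G2/M genes had 1 of 20 with a positive interaction (8 adjusted over the list alone, adjusted p = 6.32e-05, and 0.107 with an estimated correlation). The cholesterol genes had 1 of 11 (4 adjusted over the list alone, adjusted p = 0.00182, and 0.0747 with an estimated correlation). The glutathione and NRF2 list had 1 of 14 with a negative interaction, GCLM at -0.86 ± 0.10 (1 up and 4 down adjusted over the list alone, adjusted p = 0.0305, and 0.186 with an estimated correlation), with a mean of -0.16 that was 0.01 under median scaling. Its call ended with the stricter filter (0.0986) and without AA2 (0.0634), AA3 (0.063), TA3 (0.0683), AT2 (0.0543), AT3 (0.06) or TT1 (0.213). For BCL2L1 (-0.51 ± 0.19, adjusted p = 0.298), GSTA5 (-0.27 ± 0.13, 0.445) and TWIST1 (0.24 ± 0.26, 0.829) no interaction was called. That of TWIST1 was called within the dimmer set, where AA3 and AT3 stood alone for their groups (0.54, adjusted p = 0.0409), and that of BCL2L1 with array weights (-0.69, 0.045).

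Over all probes 79 had a positive and 157 a negative interaction, and 5 of 100 random assignments of the arrays, the real one included, gave as many calls. When the partner differences were kept in place and the residuals of the model without interaction were permuted, 1 of 100 orders, the real one, did so. With the brightness block and permutation within each set, 3 of 100 gave as many as the 625 called with that block. Within the dimmer set 954 were called, while limma called 0 in the brighter set (1921 at unadjusted p under 0.05). With median scaling it called 1, RNF150 (1563 at unadjusted p under 0.05). The calls of CD55, CDKN1A, GDF15, HSPA1B and SCD thus ended under both. In the brighter set and with median scaling the interactions were -1.70 and -1.36 for CD55, -1.45 and -1.33 for CDKN1A, -1.44 and -1.23 for GDF15, -1.64 and -1.30 for HSPA1B, and 1.01 and 1.22 for SCD. The count was 357 without AA1, 79 without AA2, 102 without TA1, 104 without TA3, 89 without AT1, 140 without AT2, 1221 without TT1, 106 without TT2 and 73 without TT3.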

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

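The fits with a brightness block, the fits within a brightness set, cyclic loess and the tests that permute residuals were chosen only after the data had been seen. The results here stand out because limma called an interaction, a second partner difference that depended on the first partner, for 236 probes. Positive values mean a higher signed difference, astrocytes minus NIH 3T3, after astrocytes. The interaction is also the first partner difference with astrocytes second minus that with NIH 3T3 second. For these 2 differences 43 and 2062 probes were called. More NIH 3T3 RNA on the AT than on the TT arrays, a candidate explanation of the latter, would therefore enter the interaction too. Its part in the interaction was not tested.

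Of the 10 genes with the largest negative interaction, DLK1 had -1.73, CD55 -1.63, HSPA1B -1.61, CDKN1A -1.58, HSPA1A -1.53, GDF15 -1.53, the stress-induced ZFAND2A -1.44, the transcription factor NFIB -1.37, NT5DC2 -1.34 and the amino acid transporter gene SLC3A2 -1.27. DLK1 lay near the median probe in AA and TA (5.80 and 5.86), so its interaction rests on the difference between AT and TT. The 10 genes with the largest positive interaction were RNF150 at 1.20, ARHGEF3 at 1.06, SCD at 0.95, the splicing regulator gene KHSRP at 0.86, FBXL6 at 0.83, the splicing factor gene U2AF2 at 0.82, the linker histone gene H1-2 at 0.80, GAS7 at 0.78, HGH1 at 0.77 and MYO18A at 0.76. The other tested probes of NFIB, SLC3A2 and GAS7 were not called for the interaction. Single arrays ended the calls of 10 of these 20 genes. The highest adjusted p was 0.0979 for RNF150 without TT2, 0.0721 for KHSRP without TA1 and 0.0724 for H1-2 without TA3. Without TT3 it was 0.0545 for U2AF2, 0.0612 for GAS7, 0.0627 for HSPA1A and 0.0627 for NFIB. Without AA2 it was 0.102 for MYO18A, 0.114 for NT5DC2 and 0.0579 for SLC3A2. All 20 kept their calls with the brightness block and with cyclic loess, and 18 within the dimmer set (HGH1 at 0.0725 and KHSRP at 0.0742 did not). Within the brighter set limma called none of them (1921 probes at unadjusted p under 0.05) and with median scaling RNF150 alone (adjusted p = 0.0157).

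The gene lists called for the interaction were those of ATF4 and the unfolded protein response (mean of -0.54), immediate early genes (-0.40), heat shock (-0.37), cholesterol (0.29), G2/M (0.29) and glutathione and NRF2 (-0.16, which was 0.01 with median scaling). With an estimated correlation the call of the first held (adjusted p = 0.0248), and those of the others ended, at 0.0759, 0.163, 0.0747, 0.107 and 0.186 in the same order. In the cholesterol list 1 of 11 members passed and in the G2/M list 1 of 20. The call of the glutathione list ended within the brighter set (adjusted p = 0.0538) and the dimmer set (0.0822), and that of the heat shock list with median scaling (0.202) and with cyclic loess. Without AA2, AA3, TA3, AT2, AT3 or TT1 the glutathione call also ended, at 0.213 for TT1. The fry test called 3 further lists for the interaction.

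Of 100 assignments of the 12 arrays to the 4 groups, the real one included, 5 gave as many called probes for the interaction as the 236, so by these assignments alone chance cannot be excluded. The 4 others called 292, 2014, 1535 and 372 probes, and the counts of 2014 and 1535, several times the real one, point to a structure of the samples. That structure includes the partner differences: of 15 assignments with a squared correlation of 0.44 with a partner contrast 3 gave as many, of 62 with 0.11 there was 1, and of 22 with 0 none did. The assignments thus do not measure chance for the interaction alone. With the partner differences kept and the residuals of the model without interaction permuted over the 12 arrays, 1 of 100 orders, the real one, gave as many as 236, with 197 as the highest other. With the brightness block and permutation within each set, 3 of 100 gave as many as 625, with 1963 as the highest other. Both shares lie under 0.05 and argue against chance for the count. They do not exclude it, since both tests were added after the data had been seen and the planned assignments gave 5 of 100. The loss of the calls with median scaling and within the brighter set stands beside them. In the brighter set TA and TT were 1 array each and 2 residual degrees of freedom remained, so that fit cannot decide. Of 42 followed genes called for the interaction on all 12 arrays, 0 changed sign under median scaling and 0 in the brighter set. The lost calls thus do not show that the differences were absent, and their cause was not tested. Without TT1 the count was 1221, without AA1 357, without AT2 140, without TT2 106, without TA3 104, without TA1 102, without AT1 89, without AA2 79 and without TT3 73.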

How the results depend on the processing

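The brightness block, the fits within each brightness set and cyclic loess were chosen after the data had been seen. The count of called probes for the second partner stayed within 1.5 times of 5096 under every setting run except the brighter arrays only (1668) and a minimum of 2-fold (202). With median scaling 6385 were called, 3335 of them shared. With the authors' values, no background correction, no filter and the stricter filter the counts of all 7 comparisons stayed within 1.5 times. The stricter filter ended 3 of 7 list calls for the first partner and 1 of 6 for the interaction, and no filter ended 1 for the first partner. Leaving out one array gave 4134 to 5571 for the second partner, 758 (TA2) to 2586 (TT1) for the first and 73 (TT3) to 1221 (TT1) for the interaction. It gave 910 (AT2) to 1858 for the second partner after astrocytes, 2970 (TT3) to 5040 after NIH 3T3, 12 (TA2) to 68 (TT1) for the first partner under astrocytes and 918 (TT3) to 3256 (TT1) under NIH 3T3. The correlations across probes stayed at 0.68 to 0.75 between second partner effects, 0.2 to 0.41 between first partner effects and 0.49 to 0.61 between second and first partner effects.

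With median scaling limma called 4 probes for the first partner, 1 for the interaction, 68 for the second partner after astrocytes, 0 for the first partner under astrocytes (429 at unadjusted p under 0.05) and 164 under NIH 3T3. The correlation of second partner effects was 0.84. Within the brighter arrays it called 0 for the first partner (2151 at unadjusted p under 0.05), 0 for the interaction (1921), 0 for the first partner under astrocytes (1104), 1 under NIH 3T3, 509 for the second partner after astrocytes and 803 after NIH 3T3. The correlation of first partner effects was 0.08 and that of second and first partner effects 0.39. These fits have 6 arrays and 2 residual degrees of freedom. Within the dimmer arrays, of the same size, it called 3082 for the first partner, 954 for the interaction, 291 for the first partner under astrocytes and 3354 under NIH 3T3. The correlation of second partner effects was 0.65 there. The brightness block gave 625 for the interaction and 82 for the first partner under astrocytes, where cyclic loess gave 11 and a fit of only the groups compared gave 6. Array weights gave 2820 for the first partner, 4543 under NIH 3T3 and 871 for the interaction, which was 134 with an offset of 16 and 112 with trended and robust variances. A minimum of 2-fold, which asks for more, left 6 for the first partner, 34 for the interaction, 140 for the second partner after astrocytes, 321 for the second partner after NIH 3T3, 2 for the first partner under astrocytes and 79 for the first partner under NIH 3T3. The cause of the other changes was not tested.

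The replicate block gave 2149 for the first partner, 514 for the interaction and 79 for the first partner under astrocytes. Residuals of 18 pairs of arrays with the same number correlated with r of -0.11 to 0.44, 12 of them over 0.1. Those of 26 pairs within a brightness set covered the same range, 20 over 0.1, and those of 28 pairs across sets -0.45 to 0.09. Of 4 pairs with the same number in different sets 0 were over 0.1 (-0.11 to 0.09), against 8 of 12 pairs with different numbers in one set, so the correlation followed brightness and not the number alone. A slide block was not run, since no slides are named.

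Of the second partner differences of the genes followed, 21 changed sign with median scaling, all by a common lowering. This scaling moved the median of all tested probes by -0.06, of probes above the upper quartile by -0.37 and of the 134 genes followed by -0.48, with 133 of them lowered, so the changes of sign are not particular to these genes. They were BBC3 (-0.06), GSTM3 (-0.12), CEBPD (-0.21), TIMP1 (-0.23), IFI6 (-0.14), IRF7 (-0.01), P4HA1 (-0.24), BNIP3 (-0.11), HK2 (-0.10), DDIT4 (-0.06), CTH (-0.19), KRT18 (-0.35), HEY1 (-0.12), JAG1 (0.00), CCNA2 (-0.09), PHLDA1 (-0.07), SPRED1 (-0.10), BAG3 (-0.02), MTF1 (-0.11), MUC1 (-0.18) and TUBB3 (-0.16). Of the 118 of these genes called for the second partner, 75 kept direction and call and 22 lost the call, and 5 others gained one. For the first partner 67 of 67 called genes lost the call with median scaling, and for the interaction 41 of 42. Within the brighter arrays 41, 67 and 42 lost the call for the second partner, first partner and interaction. Of the 20 genes with the largest second partner difference all kept their calls under median scaling, the brightness block, cyclic loess, the dimmer arrays and leaving out any one array, and 19 within the brighter arrays. Leaving out one array, the called lists kept their calls in 156 of 156 tests for the second partner, 71 of 84 for the first and 66 of 72 for the interaction, and uncalled lists gained one in 1, 7 and 3 tests. Signal over background limits genes near the median probe of 5.94, whose differences are understated.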

Other observations

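The tests of brightness, of partner RNA, of the human share of RNA and of the melanocyte genes were chosen only after the results were seen, as were the lists of melanocyte, fatty acid synthesis and histone genes. The counts over random assignments and splits were planned.

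The second partner difference was called for 5096 probes. Of 100 random assignments of the arrays, the real one included, 1 gave as many, with 975 as the highest other count. These assignments did not keep the first partner difference or the brightness sets in place. They thus do not measure chance for the second partner alone and cannot exclude it, although the real count lay above every other. After astrocytes 1 of the 10 splits of 6 arrays, the real one, gave as many as 1467, against 1 in the highest other, and after NIH 3T3 1 of 10 gave as many as 4483, against 0 in the highest other by limma, which is too few splits for a share under 0.05. A lower share of human RNA with astrocytes may contribute: mean signal with NIH 3T3 second was 1.244 times that with astrocytes second in the brighter set and 1.412 times in the dimmer set, but a different yield of labelled RNA would do the same, so the explanations cannot be told apart. A response of the tumour cells to the partner and binding of mouse RNA to the probes stay open beside these, and neither was tested.

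The first partner difference was called for 1430 probes, and with median scaling for 4. Of 100 random assignments, the real one included, 1 gave as many as 1430, with 354 as the highest other count. These assignments kept neither the second partner difference nor the brightness sets in place. They thus do not measure chance for the first partner alone and cannot exclude it for the average over second partners. Under NIH 3T3, 1 of 10 splits gave as many as 2062, with 10 in the highest other, and under astrocytes 1 of 10 gave as many as 43, with 0 in the highest other by limma, again too few splits for a share under 0.05. The brightness of the arrays as the whole cause under NIH 3T3 is argued against by the fit with the brightness block, which called 2374 probes. More NIH 3T3 RNA on the AT arrays is a candidate explanation there: the 5 genes seen only with NIH 3T3 second, DLK1 (1.67), RAB42 (1.28), GLT8D2 (0.81), ZFHX4 (0.79) and DCN (0.61), were all higher in AT than in TT, with a median log2 difference of 0.81. Mean signal was also lower in AT than in TT. It was 181 against 222.2 in the brighter set, where TT was 1 array, and 118.7 against 142.9 in the dimmer set, where AT was 1 array. A different yield of labelled RNA would lower the signal as well, so the explanations cannot be told apart. Under astrocytes the 19 probes seen only with astrocytes second had a median of 0.15, with 14 of 19 above 0, APOE at -0.45 and CHSY3 at 0.67, which leaves more astrocyte RNA in AA open beside a lasting effect of the first partner on the tumour cells, untested with either second partner.

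Many genes of the melanocyte lineage were high on arrays labelled as a lung cancer line: 13 of 19 lay above the upper quartile of all probes, 68.4%, against 10.7% of epithelial and lung genes. Of the 19, PMEL (5.97), SLC45A2 (5.96), OCA2 (5.80), BCL2A1 (5.89), PAX3 (6.13) and SLC24A5 (6.13) lay below that quartile of 6.15. MLANA (6.28) and ST8SIA1 (6.21) lay just above it. Group means in AA, TA, AT and TT were 8.29, 8.95, 8.91 and 9.92 for TYR, 8.81, 8.91, 8.76 and 9.46 for SOX10 and 10.21, 10.56, 10.86 and 11.56 for GPNMB. By contrast, EPCAM (5.90), CDH1 (5.97), KRT8 (5.83) and NKX2-1 (5.79) lay near the median probe and KRT18 (9.01), MUC1 (7.70) and SFTPA1 (7.66) above it. RNA of one of the mouse partners alone is argued against, since TYR, SOX10, MITF and GPNMB lay at least 1.27 above the median probe in every group. Tumour cells other than the labelled line remain a candidate explanation for the 68.4%. This cannot be told apart from expression of these genes by the labelled line or by unlabelled cells common to all cultures, since no array holds either alone. The labels name no mouse partner common to all groups.

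The p-values of the 3 added lists are adjusted over these lists within a comparison. In the melanocyte list 13 of 17 tested genes fell with astrocytes second (13 adjusted over the list alone, camera adjusted p = 1.34e-07, and 0.0432 with an estimated correlation) and 12 fell with astrocytes first (14 adjusted over the list alone, adjusted p = 1.24e-12, and 0.00994 with an estimated correlation), with means of -0.39 and -0.33 that were -0.72 and -0.38 with median scaling. In the interaction 1 of 17 was positive (5 adjusted over the list alone, adjusted p = 0.00012, and 0.0771 with an estimated correlation). The list shares EDNRB, BCL2A1 and SOX10 with other lists.

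In the fatty acid list 3 of 14 genes, SCD (0.95 ± 0.14), ACLY (0.74 ± 0.15) and SREBF2 (0.64 ± 0.13), had a positive interaction (7 positive and 1 negative adjusted over the list alone, adjusted p = 0.00012, and 0.0442 with an estimated correlation), with a mean of 0.31, or 0.51 with median scaling. For the second partner 1 rose and 5 fell (adjusted p = 0.224) and for the first partner 1 rose and 3 fell (1 and 5 adjusted over the list alone, adjusted p = 0.0448, and 0.178 with an estimated correlation). Of the histone genes 12 of 49 rose and 9 fell with astrocytes second (13 and 11 adjusted over the list alone), with a mean of 0.13 that was -0.06 with median scaling. The list was not called by camera of limma (adjusted p = 0.224), and H2BC6 rose by 1.96 ± 0.12 while H2BC12 fell by 0.73 ± 0.07. For the first partner 3 rose and 4 fell (5 and 7 adjusted over the list alone, adjusted p = 0.297), and in the interaction 1 was positive (2 adjusted over the list alone, adjusted p = 0.00012, and 0.0771 with an estimated correlation).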
